A study of Mus musculus with 3 samples.

How the data were processed

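The series mapped 5-hydroxymethylcytosine (5hmC), the oxidised form of 5-methylcytosine made by TET enzymes, in mouse bone marrow cells. Per the labels, there were 3 samples: 1 of normal marrow and 2 of an acute myeloid leukaemia (AML) called NIDF-AML, induced by IDH2 R140Q, the NPM1 mutant NPMc, DNMT3A R882H and FLT3-ITD. Per the labels' protocols, 5hmC in sonicated DNA was tagged with an azide-bearing glucose by β-glucosyltransferase and coupled to biotin by click chemistry. The tagged fragments were captured on avidin and sequenced as paired ends on an Illumina HiSeq2000. The mm10 genome build comes from the submitters' processing notes. The aligner is not given in the sources used here.

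The deposited peak lists of the 2 leukaemia samples were used, and no list for normal marrow was analysed here. Each line of a deposited list has 3 columns, a chromosome, a start and an end, and carries no measured value of the peak. Per the file headers, the authors called the peaks with PICS (Probabilistic Inference for ChIP-seq), which models the forward and reverse reads around each enriched site. The header settings were a read length of 99 bp, a fragment length of 200 bp, 250 bp windows moved by 20 bp and minimums of 3 reads per window and 10 per region. They also name a maximum of 5 binding sites per gene and 5000 bp of upstream padding for genes. Any score cutoff is not given in the sources used here.

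Both headers name the library with index 4 as the treatment. The control is index 5 for the list of leukaemia replicate 1 and index 6 for the list of replicate 2. The treatment index is thus shared while the control index differs between the lists, so index 4 may be normal marrow. The labels list 3 samples, all of 5hmC, and no input, so the controls may be other 5hmC libraries. The sources used here do not say which of the 3 samples carries which index, so every value below belongs to "the index 4 library". All 223267 lines were the same in both lists. They were therefore counted as 1 list, with no spread between replicates and no test between leukaemia and normal marrow. Read depth is unknown. Intervals are exact Poisson or Wilson binomial intervals at 95%, treat peaks as independent, and cover counting error only. The X to autosome density ratios have exact intervals for a ratio of Poisson rates, with the same limits. Intervals of ratios for X genes against autosomal genes of like span are 95% bootstrap intervals from redrawing genes. They describe the spread among these genes, which are not replicates.

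Of the lines, 14799 (6.63%) repeat an earlier line, and 1 interval occurs up to 22 times. Genes lay closer together at repeated intervals: 89.75% of the 13447 repeated intervals had at least 2 annotated genes within 5 kb, against 17.95% of the intervals listed once. Each interval was counted once, which left 208468 peaks. This was decided after the data were seen, and the values with repeated lines kept are among the alternatives. All starts and ends equalled their own single-precision value, against 25.75% for arbitrary positions. Positions above 16777216 bp are multiples of 2, and those above 134217728 bp are multiples of 16. Of the starts and ends, 31838 lie up to 16777216 bp, where every position is possible. From 67108864 to 134217728 bp there are 192224, all multiples of 8, and 47832 lie farther along. Widths and short distances are therefore coarse for most peaks, and most so toward the ends of long chromosomes. The limit of 5 sites per gene named in the header does not bound the list, since 71 genes held more than 100 peaks and the most in 1 gene was 340.

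Genes came from a RefSeq table of assembly GRCm38.p6, whose chromosomes are those of mm10. It gives 1 span per gene, without strand or exons. Gene models that start below 3 Mb on chromosomes other than Y lie on scaffolds and were left out (108 models), leaving 21779 protein-coding genes. A peak belonged to every gene whose span held its midpoint, so overlapping genes share peaks. Without strand, exons or genome sequence, promoters, exons, GC and CpG content could not be assigned, and with no score the planned score cutoffs could not be applied.

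Expected values came from 100 random placements of the peaks between the first and last feature of their own chromosome. Assembly gaps inside that range were not excluded. A set of 16 gene lists with 481 different genes was fixed before the data were examined, and all 481 were found in the table. For each list, the share of genes with a peak in the body or within 5 kb was ranked among 10000 random lists of the same size, matched on gene span in 20 bins. This is a permutation of list membership among genes of like span, and its smallest possible p is 0.0002. Two-sided p-values were adjusted over the 16 lists by the Benjamini-Hochberg method, with 0.05 as the threshold. Genes are not replicates, so these ranks describe this list of peaks. The median number of peaks per kb of each list was fixed beforehand as a further measure. Peaks were also simulated uniformly along each chromosome, with all 21779 genes, and 4 of the 16 lists were given 3-fold density. The share recovered 0 of the 4 and the median per kb recovered all 4. Neither called any of the 12 lists left alone. The real peaks were far more clustered than the simulated ones, so these counts do not carry over to them. The share is close to saturated for long genes, and both measures are therefore given.

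The genes named were fixed by rule beforehand: the 10 genes with the most peaks per kb among those with at least 5 in the body, the 10 with the most peaks, every Hoxa gene and Meis1, and in each list the 3 members with the most peaks within 5 kb. The part of the rule on peak scores at promoters could not be applied, and some genes that the rule names are not reported here. Further list members, such as Kit, Flt3, Tet2, Vegfa, Npm1 and members without a peak, were named after their values were seen. Alternatives were gene bodies alone, peaks per kb, all annotated genes, autosomes only, other windows, a circular shift of each chromosome's peaks, lists matched also on the peak density of the 500 kb flanks, and each replicate left out. The circular shift, the flank matching, the autosomes for gene lists, the gene ends, the densities within gene bodies and the repeated lines were added after the data were seen. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used.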

Results

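The data were peaks of 5hmC in mouse bone marrow, from a series of normal marrow and NIDF-AML samples. The series title names Hoxa9/Meis1 and hypoxia pathways as the targets of the IDH2 and NPM1 mutations, so these genes were examined by name. The 2 leukaemia samples contributed lists with 100% of their 223267 lines in common, which were counted as 1 list of 208468 peaks. That list belongs to the index 4 library, and whether index 4 is leukaemia or normal marrow is not given in the sources used here. Both headers share the treatment index and differ in the control index, so index 4 may be normal marrow. No comparison between leukaemia and normal marrow was therefore made, and no value below has a replicate. Read depth is unknown, so the absence of a peak means only that none was listed. The control libraries may also be of 5hmC. If they entered the calling, a listed peak could mean more 5hmC than in the control. An absent peak could then mean no excess over the control. The peaks had a median width of 65 bp (quartiles 49 and 81 bp) and together covered 14.2 Mb. These widths are coarse because of the rounded positions.

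5hmC peaks of the index 4 library lay mostly in genes. Protein-coding gene bodies held 134703 peaks, 64.6% of the total (Wilson interval 64.4 to 64.8%), where random placement gave 41.4%, a 1.56-fold excess. Sequence outside genes but within 5 kb of one held 9.50% (Wilson interval 9.37 to 9.62%) against 6.00%, a 1.58-fold excess. Sequence farther than 5 kb from any protein-coding gene held 25.9% against 52.6%, or 0.492 of the random share. For each of these shares, 0 of 100 random placements were as extreme. Of the 21779 protein-coding genes, 14515 (66.6%) had a peak in the body, with a median of 2 peaks per gene.

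The density of peaks changed with distance from the nearest gene end. It was highest inside genes at 1000 to 2500 bp from an end, at 2.89 times the random placement (exact Poisson interval 2.84 to 2.94). It was lower in the first 500 bp on both sides of the end, at 1.93 times inside (1.87 to 2.00) and 1.83 times outside (1.77 to 1.90). Outside genes it was 2.14 times at 500 to 1000 bp and 1.11 times at 5000 to 10000 bp, and it fell to 0.443 times at 50000 to 200000 bp. Inside long genes it was 0.969 times at 50000 to 200000 bp from an end. Only long genes reach that distance, so the classes inside genes hold different genes. Gene length and position within a gene were therefore not separated. The gene table has no strand, so both ends are pooled and the start of a gene cannot be separated from its end. Overlapping protein-coding genes were merged for these distances, so a gene end that lies inside another gene was not counted as an end.

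**Figure D1:**
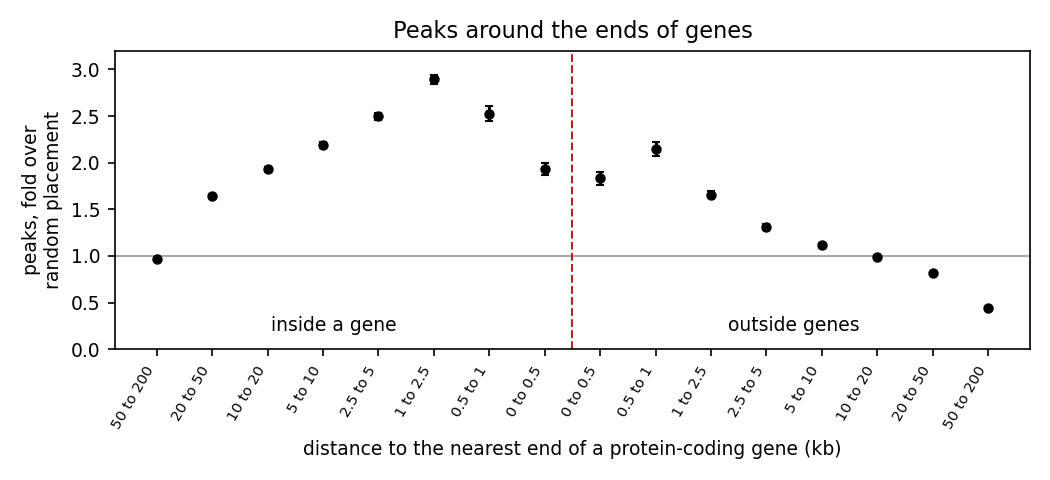
Fold of 5hmC peak number over random placement (y axis) by distance from the nearest end of a protein-coding gene (x axis, kb, inside and outside the gene), with exact Poisson intervals. Overlapping genes were merged. The fold was 2.89 at 1000 to 2500 bp inside genes and 1.93 in the first 500 bp inside.

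The genes with the most peaks were long. Foxp1, a forkhead transcription factor, held 340 peaks (exact Poisson interval 305 to 378) over its 597 kb on chromosome 6 (98925342 to 99522746). Gse1 held 255 peaks, Arid1b, a subunit of a chromatin remodelling complex, 235, and Tiam1, an activator of the GTPase Rac, 234. Foxn3 held 227, Asap1 203 and Prkce, a protein kinase C, 199. Runx1, a transcription factor needed for blood stem cells and often mutated in AML, held 184 (158 to 213) over 225 kb on chromosome 16 (92601466 to 92826074). Cmip held 182 and Igf1r, a growth factor receptor, 181. Of all protein-coding genes, 71 held more than 100 peaks.

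Among genes with at least 5 peaks in the body, those with the most peaks per kb were short. Zbtb12 had the highest density of these, with 5 peaks on chromosome 17 (34894559 to 34896867), or 2.17 per kb. Cd79a, a signalling chain of the B cell receptor, held 9 peaks in 4.36 kb on chromosome 7 (24897497 to 24901858), or 2.06 per kb, and Zmynd10 also held 9, or 2.02 per kb. Rhbdl1 held 5, Ucp2, a mitochondrial carrier protein, 10 and Rpl18 8. Lyz2, the lysozyme of granulocytes and macrophages, held 7 peaks on chromosome 10 (117277541 to 117282272), or 1.48 per kb. Ncf1, a subunit of the phagocyte NADPH oxidase, held 14 on chromosome 5 (134220053 to 134229628), or 1.46 per kb. LOC100504180 held 5 and Ecm1 8. The mean over all protein-coding genes was 0.131 peaks per kb of body. These densities rest on few peaks: the exact Poisson interval of the 5 peaks of Zbtb12 is 1.62 to 11.7 peaks. With repeated lines kept, Rpl18 held 22 peaks, Zmynd10 18, Cd79a 16, and Zbtb12 and Rhbdl1 10 each.

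Genes of granulocytes and monocytes had the highest median density of the 16 gene lists. All 38 had a peak within 5 kb (100% against 69.6% in random lists of like span), and their median was 0.507 peaks per kb against 0.141, a ratio of 3.60. For every list, the random lists drew on all protein-coding genes of like span. These include families with few peaks, such as olfactory receptor genes, of which 6.53% had a peak within 5 kb. How far such families lower the expected values was not measured. Spi1, the master regulator of myeloid cells, the macrophage receptor gene Csf1r and the monocyte regulator Irf8 had 34 peaks each within 5 kb. Genes of FLT3 and KIT cytokine signalling followed, with 40 of 41 genes (97.6% against 79.9%) and a median ratio of 3.48. In that list Bcl2, a survival gene, had 64 peaks, the kinase gene Pik3cd 59, the adaptor gene Grb2 57, Kit 38 and Flt3 34. Stem and progenitor transcription factors had a peak at 28 of 29 genes and a ratio of 2.99, with 188 at Runx1, 183 at Etv6 and 96 at Runx2.

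The list of enzymes that methylate cytosine or oxidise and remove 5-methylcytosine also holds readers and related genes, such as Idh1, Idh2 and Gadd45a. It had a peak at 25 of 26 genes and a ratio of 2.87. Tet3 had 67 peaks, Dnmt3a 63, Dnmt1 37, Tet2 25, Idh2 21 and Tet1 17. B lineage genes had a peak at 25 of 26 and a ratio of 2.80, with 177 at Bach2, 56 at Ebf1 and 48 at Pax5, and with none at Cr2. Ribosomal protein genes had one at 52 of 54 and a ratio of 2.64, with 16 at Rpl18 and 10 at Rplp0. Hypoxia response genes had a peak at 38 of 40 (95% against 78.9%) and a ratio of 2.36. The glycolytic genes Hk1 and Pfkfb3 had 59 and 49 peaks and Mxi1, a MYC antagonist, 46. Vegfa had 20, Egln1, an oxygen-sensing hydroxylase, 27 and Hif1a 2, while Pgk1 and Epo had none.

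Genes of neurons, hepatocytes and marrow stroma had a peak less often than random lists. Neuronal genes had a peak at 15 of 25 (60% against 81.3%), and their median was 0.00655 per kb against 0.0986. Snap25, Gad1 and Syt1 had none, and Camk2a had 21, Dlg4 18 and Rbfox3 14. Hepatocyte genes had one at 14 of 25 (56% against 77.0%), with none at Alb and with 23 at Ass1 and 11 at Hpd. Marrow stroma and endothelium genes had one at 17 of 28 (60.7% against 80.5%). In that list Pecam1 had 50 peaks, Pdgfrb 24 and Cdh5 15, and Cxcl12, Kitl, Lepr, Tek and Emcn had none.

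Over the 16 lists, the share of genes with a peak was above random lists in 8 and below in 3, by two-sided permutation p-values over random lists with Benjamini-Hochberg adjustment. The adjusted permutation p was 0.0016 for the granulocyte and monocyte list and for the ribosomal list, 0.0128 for cytokine signalling, 0.032 for hypoxia response and for B lineage genes, 0.0384 for stem and progenitor factors and 0.0419 for the cytosine enzymes. Megakaryocyte and platelet genes were above by share (21 of 22, adjusted permutation p = 0.0361), with 89 peaks at Fli1, 49 at Itgb3 and 32 at Vwf, but not by median per kb (ratio 1.38, adjusted p = 0.52). Neuronal genes were below with adjusted permutation p = 0.0361, stroma and endothelium with 0.038 and hepatocyte genes with 0.0462. By median per kb the other 7 lists stayed above and neuronal genes stayed below (adjusted permutation p = 0.0052), while hepatocyte genes (0.0497 per kb against 0.160, a ratio of 0.311, adjusted permutation p = 0.0679) and stroma and endothelium genes (ratio 0.757, 0.592) did not pass. On autosomes alone hepatocyte genes were below by median per kb (ratio 0.301, adjusted permutation p = 0.0301). By median per kb of the body alone, stroma and endothelium genes were below (0.213, 0.0249). With a peak required in the gene body, 3 lists no longer passed by share although their ratios to random lists barely moved: the cytosine enzymes went from 1.221 to 1.217, stem and progenitor factors from 1.217 to 1.209 and megakaryocyte genes from 1.295 to 1.297. With lists matched also on the peak density of the 500 kb flanks, granulocyte and monocyte genes (ratio 1.24) and ribosomal genes (1.26) passed by share. The other 6 lists above did not, at share ratios of 1.03 for hypoxia response, 1.07 for cytokine signalling, 1.09 for B lineage, 1.1 for the cytosine enzymes, 1.14 for stem and progenitor factors and 1.16 for megakaryocyte genes. Neuronal, hepatocyte and stroma and endothelium genes did not pass there, at share ratios of 0.752, 0.771 and 0.785 against 0.738, 0.727 and 0.754 without that matching. The same matching lowered the ratios of median per kb to 2.21 for granulocyte and monocyte genes, 1.94 for cytokine signalling, 2.25 for stem and progenitor factors, 2.13 for the cytosine enzymes and 1.61 for ribosomal genes, which still passed. It lowered them to 1.44 for hypoxia response and 1.625 for B lineage genes, which did not (adjusted permutation p = 0.0828 for each).

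Of the lists without Hox genes, 4 passed by neither measure over all chromosomes. Erythroid genes had a peak at 23 of 30 (76.7% against 72.1%, adjusted permutation p = 0.871), with 50 at Zfpm1, 43 at Sptb and 25 at Rhd. T and NK lineage genes had one at 27 of 33 (81.8% against 79.2%, adjusted permutation p = 0.969), with 43 at Notch1 and 30 at Lef1. Histone demethylases that use 2-oxoglutarate had one at 17 of 20 (85% against 84.3%), with 52 at Phf2, 50 at Kdm2b and 40 at Jmjd1c. Recurrently mutated AML genes had one at 32 of 35 (91.4% against 84.0%, adjusted permutation p = 0.431), and 15 of the 35 are also in other lists. On autosomes alone this list passed by median per kb (ratio 2.20, adjusted permutation p = 0.00853). Among them Dnmt3a had 63 peaks and Npm1 2.

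**Figure D2:**
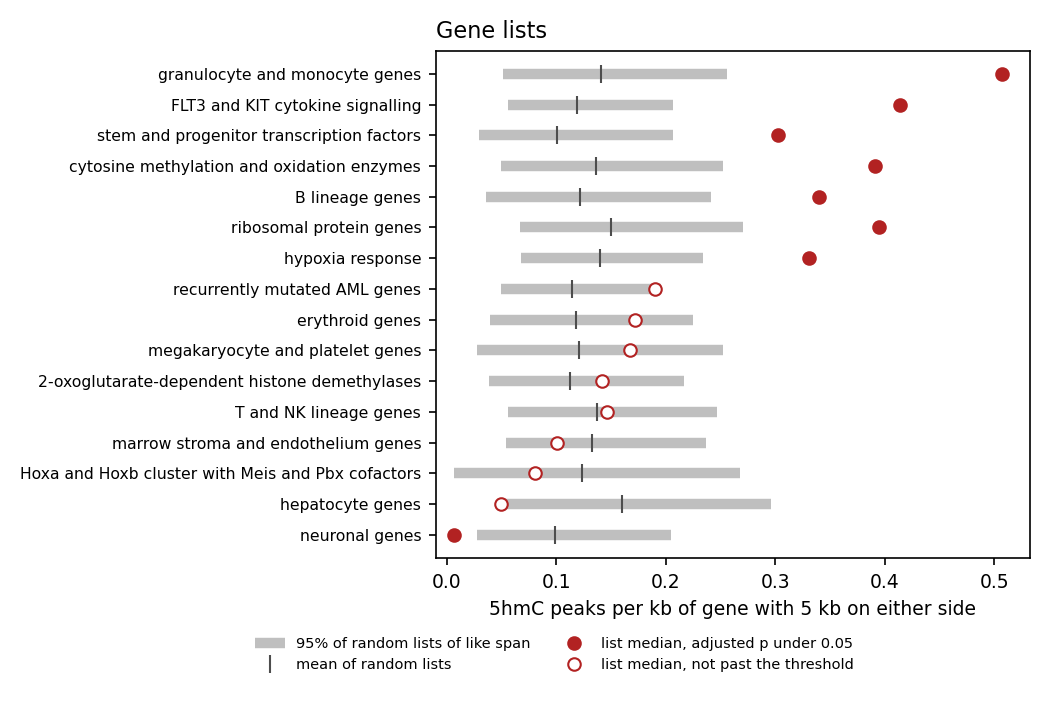
Median number of 5hmC peaks per kb of gene with 5 kb on either side (x axis) for the 16 gene lists (y axis); points are list medians, filled where adjusted p is under 0.05, grey bars span 95% of random lists of like span and ticks are their means. Granulocyte and monocyte genes lie highest at 0.507 and neuronal genes lowest at 0.00655.

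The Hoxa cluster, whose posterior genes together with Meis1 drive many acute leukaemias, carried peaks in its genes from Hoxa2 to Hoxa7 and none from Hoxa9 to Hoxa13. The 37.8 kb from Hoxa9 to Hoxa13 on chromosome 6 (52223097 to 52260880) held 0 listed peaks. Hoxa3 had 11 peaks in its body, Hoxa4 and Hoxa6 had 2 each, and Hoxa2, Hoxa5 and Hoxa7 had 1 each. Hoxa3 spans other Hoxa genes in the gene table, so some peaks count for several genes. With repeated lines kept, Hoxa3 held 28, Hoxa6 7, Hoxa4 4, Hoxa5 and Hoxa7 3 each and Hoxa2 2. Hoxa9 (52223097 to 52227370) had none in its body and 1 within 5 kb (52219312 to 52219392), and Hoxa10, Hoxa11 and Hoxa13 had none within 5 kb. A peak within 5 kb was found at 76.1% of genes of like span to Hoxa10, 68.9% for Hoxa11 and 58.95% for Hoxa13. Genes without one were thus a minority at these spans, though not a rare one. Genes of like span to Hoxa9 had a median of 2 peaks.

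Meis1, the cofactor of Hoxa9, held 6 peaks (exact Poisson interval 2.20 to 13.1) over 139 kb on chromosome 11 (18880428 to 19019651). Genes of like span had a median of 13 peaks, and 63.5% of them had more. The cofactor gene Pbx2 had 15 peaks within 5 kb. The list of Hoxa and Hoxb genes with Meis and Pbx cofactors had a peak at 18 of 27 genes (66.7% against 69.8%), with adjusted permutation p = 0.969 by share and 0.671 by median per kb. Whether these positions differ between leukaemia and normal marrow was not tested.

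**Figure D3:**
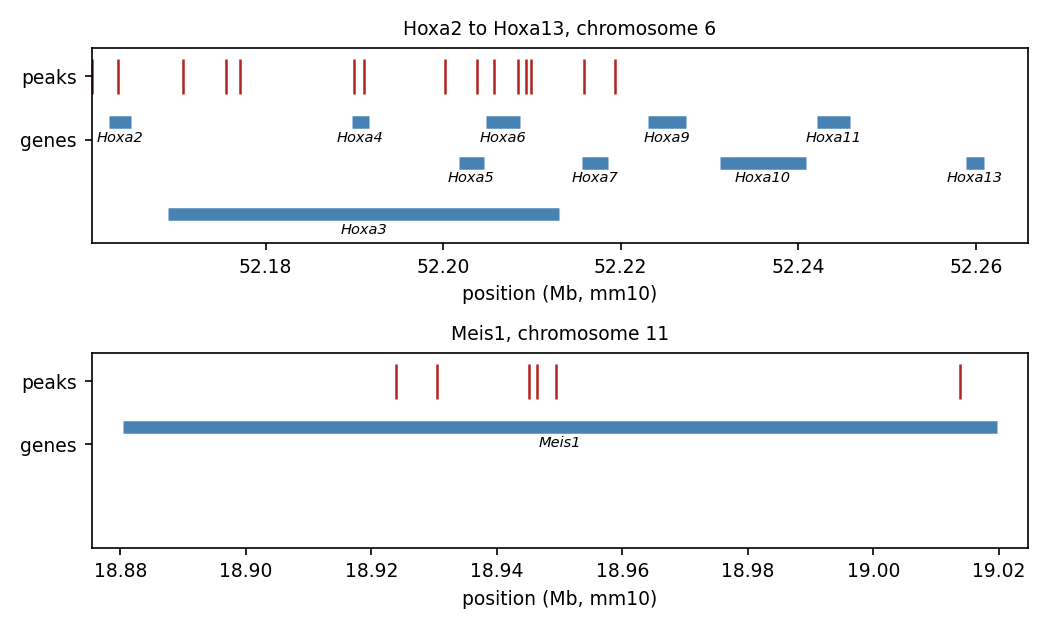
Maps of the Hoxa2 to Hoxa13 part of the Hoxa cluster on chromosome 6 and of Meis1 on chromosome 11, with position in Mb of mm10 on the x axis; red lines are 5hmC peaks and blue bars gene spans. No peak lies from Hoxa9 to Hoxa13, and Hoxa3 holds 11 and Meis1 6.

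Chromosome X carried few peaks. It held 1104 peaks, or 6.58 per Mb (exact Poisson interval 6.20 to 6.98), against 86.2 per Mb over the 19 autosomes, a ratio of 0.0763 (0.0718 to 0.0809). Within gene bodies the densities were 12.1 and 136.5 per Mb, a ratio of 0.0887 (0.0814 to 0.0964). Of the 963 X-linked protein-coding genes, 29.6% had a peak within 5 kb, against 76.1% of autosomal genes. Among autosomes, chromosome 11 had the highest density with 133 per Mb (131 to 135) and chromosome 3 the lowest with 57.2 (56.1 to 58.4). Chromosome Y held 176 peaks, or 1.94 per Mb. Assembly gaps were not removed from these lengths.

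**Figure D4:**
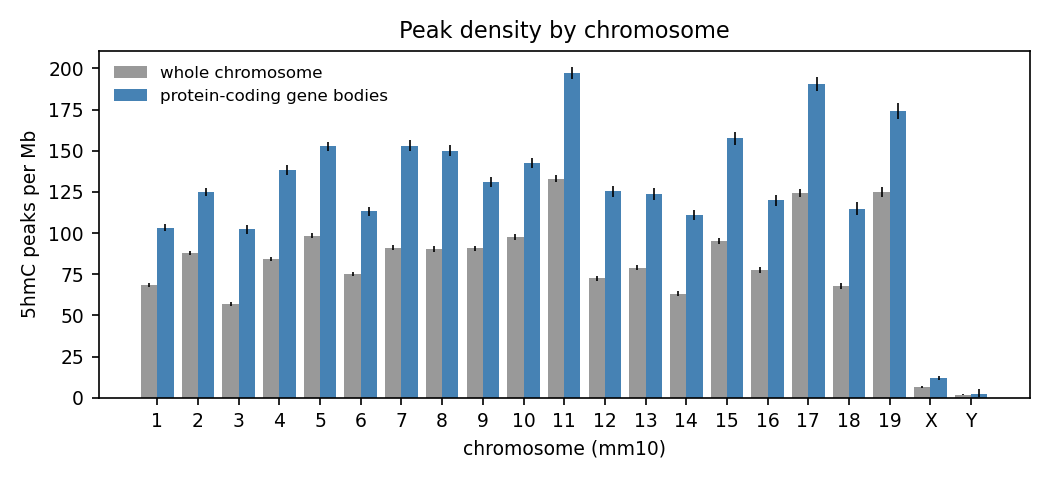
5hmC peaks per Mb (y axis) of each whole chromosome (grey bars) and of its protein-coding gene bodies (blue bars), by chromosome on the x axis, with exact Poisson intervals. Over the whole chromosome, X lies at 6.58 peaks per Mb and chromosome 11 at 133.

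The last part of chromosome X differed from the rest. Mid1 (169685199 to 169990798), which spans the pseudoautosomal boundary in laboratory mice, held 16 peaks, all in its last 20.1 kb, and the 285.5 kb of the gene before them held none. From the first Mid1 peak to the end of X there were 32 peaks, and the rest of X held 1072, or 6.42 per Mb. Of the 176 peaks on Y, 67 lay past 90 Mb. Mid1 was chosen after its values were seen.

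**Figure D5:**
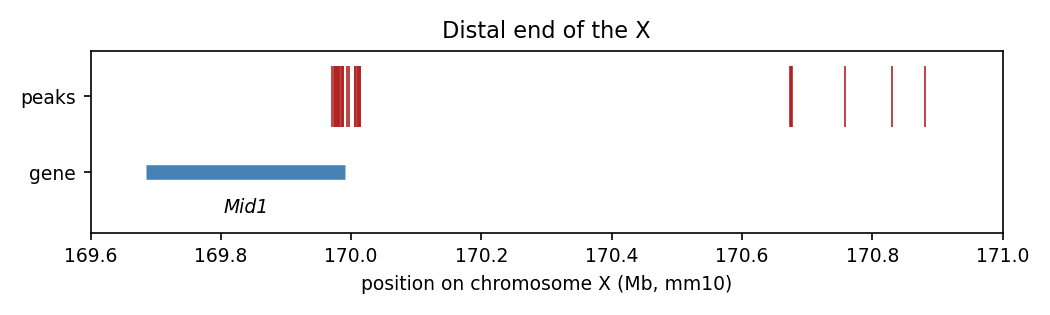
The distal end of chromosome X, with position in Mb of mm10 on the x axis; red lines are 5hmC peaks and the blue bar is the span of Mid1. The 16 peaks of Mid1 lie in its last 20.1 kb.

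Peaks also gathered in regions. The 2412 autosomal windows of 1 Mb held a median of 46 peaks and at most 577, and 113 windows (4.69%) held none, where random placement left 0.3. The variance of the counts was 117 times their mean, against 5.44 for random placement, a ratio of 21.5. The highest of the 100 placements reached 5.54.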

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

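A peak required in the gene body, the median per kb and the 100 kb windows were planned. The alternatives with repeated lines, circular shift, flanks, gene ends, densities within gene bodies (for lists and for chromosome X) and autosomes for gene lists were chosen after the data were seen. The excess of peaks inside genes stayed between 1.45-fold (all annotated genes) and 1.59-fold (repeated lines kept), the X to autosome ratio between 0.0761 and 0.0887, and the clustering ratio was 16.2 in 100 kb windows and 21.1 with repeated lines. Leaving out either replicate changed nothing, because the lists are identical, and so says nothing about stability. Of the gene lists, 8 were above and 3 below random lists by share. With a peak required in the gene body 5 were above. The median per kb left 7 above and 1 below, and a peak within 2.5 kb of either gene end left 6 above and 1 below. At gene ends, stem and progenitor factors (ratio 1.215, adjusted permutation p = 0.2685) and megakaryocyte genes (1.343, 0.08735) did not pass. The median per kb of the body alone left 7 above and 2 below. Matching on span and flanking peak density left 2 above and 0 below by share, and 5 above and 1 below by median per kb. The 3 lists below kept share ratios of 0.752, 0.771 and 0.785 there. By median per kb, marrow stroma and endothelium genes had a ratio of 1.02 (adjusted permutation p = 0.907) with flanks matched and 0.757 (0.592) without, passing in neither. Against the share, the direction thus reversed with both choices changed, and the cause was not tested. By median per kb of the gene body alone, without flank matching, these genes were below (ratio 0.213, adjusted permutation p = 0.0249). Over the single lists and their alternatives other than leaving out a replicate, 99 results were the same, 27 lost the threshold in the same direction, 1 (stroma and endothelium, above) lost it with the direction reversed and 1 gained it, the recurrently mutated AML genes on autosomes alone by median per kb (ratio 2.20). The 99 include lists that passed neither by share nor under the alternative, such as erythroid genes. Every loss came from a list that passed by share, so the 99 overstate how well the passing lists held. Of 74 counts for named genes, 6 left the exact Poisson interval of the count with repeated lines kept: Bcl2 from 64 to 88, Dnmt3a from 63 to 92, Pax5 from 48 to 70, Hoxa3, Rpl18 and Zmynd10. In all, 13 rose by more than 1.5 times, most from small counts, such as Cd79a from 9 to 16, Pbx2 from 6 to 12 and Hoxa6 from 2 to 7. The variants with score cutoffs, transcription starts, promoter widths, matched GC or CpG and assembly gaps, and the GC and CpG content of peaks, were not run, since no score, strand or genome sequence was used here. No paired analysis was possible because the lists used were identical and belong to a single library. Depth is unknown and limits what an absent peak can mean.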

Other observations

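The tests on gene families, long genes, identical lists, and chromosome X other than that on marrow genes were chosen after the data were seen. Families best known from other tissues had few peaks on autosomes. Olfactory receptor genes had one within 5 kb at 72 of 1103 genes (6.53% against 30.8% in random lists of like span) and vomeronasal receptor genes at 12 of 351 (3.42% against 45.3%). Cytochrome P450 genes had one at 40 of 99 (40.4% against 82%), keratin genes at 21 of 53 (39.6% against 75.5%) and beta-defensin genes at 10 of 42 (23.8% against 66.5%). Protocadherin genes had one at 34 of 67 (50.75% against 80.9%). Overlapping or adjacent genes share peaks, so family members counted here need not have separate peaks. The Hoxa to Hoxd genes had one at 15 of 39 (38.5% against 72.4%), made up of 8 of 11 Hoxa, 5 of 10 Hoxb, 2 of 9 Hoxc and 0 of 9 Hoxd genes. Rab GTPase genes had one at 63 of 65 (96.9% against 84.1%). Interleukin receptor genes had one at 35 of 36 (97.2% against 85.1%), which equals the upper bound of the range of 95% of random lists. In all, 10 families were tried, without adjustment, and 1 is not given.

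Some very long genes had no peak within 5 kb. The longest such autosomal genes were Cntn5 (1.27 Mb), Tenm2 (1.23 Mb), Csmd3 (1.21 Mb) and Cdh12 (1.15 Mb), which encode membrane proteins best known from neurons. The 10 intervals listed most often, with 22 lines each, lay at 37815892 to 37841720 on chromosome 18, under 24 overlapping protein-coding genes.

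Chromosome X had few peaks, and the shortness or number of its genes did not account for this. X genes had 0.0924 of the peaks of autosomal genes of the same span (bootstrap interval over genes 0.0768 to 0.110, as for the ratios that follow). A lack of marrow genes did not account for all of it either: the 18 X-linked members of the fixed lists, which include the neuronal Syn1 and the hepatocyte gene F9, had a ratio of 0.279 (0.0660 to 0.593), and the 16 without those had 0.296 (0.0562 to 0.637), against 1.45 for autosomal members. These intervals lie below 1 but not below the bound of 0.5 set in advance, which was stricter than needed, and Bcor alone held 35 of the 60 peaks (0.130 without it, a gene picked by its value, whose removal must lower the ratio). A single X copy with peak number in proportion to copies would give about 0.5, and 0.0763 was measured. A single copy that takes regions under the caller's read minimum may still contribute, since the end of Mid1 had 794 peaks per Mb, but that segment was bounded by its own first peak, the sex of the animals is not given in the labels used here, and no biological explanation was tested.

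The gene lists differed in peak density, and 2 technical explanations were tested. By median per kb, peak density of the surrounding region did not account for all of it, since 5 lists stayed above lists matched on span and flanks: granulocyte and monocyte, cytokine signalling, stem and progenitor, cytosine enzyme and ribosomal genes. By share, the same matching left only 2 above, granulocyte and monocyte genes and ribosomal genes, and 0 below. For the other lists called by share, the surrounding region thus remains a possible explanation of that measure. Peaks outside the gene but within 5 kb did not account for it, since 7 lists were above by peaks per kb of the body alone. Peaks of overlapping genes still count in the body, so their part could not be separated. CpG content and mappability were not tested and could contribute, and no biological explanation was tested because the list is of 1 library.

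The same list stands for both leukaemia samples, with index 5 as the control in one header and index 6 in the other, and 100% of the lines were the same. Whether use of the control library in the calling would have changed any line cannot be judged, since the lists hold no score and no score cutoff is given. That the control library left no mark on the list and that 1 list was deposited under both names cannot be told apart, because no score, count or second list was used here.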
